A study of Mus musculus with 9 samples.

How the data were processed

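The values were FPKM per gene as computed by the authors, in a single deposited table of 30350 genes and 9 libraries. The table does not name its unit, which was inferred from the values: within a gene they were whole multiples of what a read is worth, and that worth fell with the gene's length. Relative depth came from the most frequent ratio of values below 0.5 FPKM between libraries, and every one of 205016 values above 0 then came out as a whole number of reads within 0.01 (100%). A test on made-up reads, lengths and depths recovered 100% of genes. Gene lengths of the reference fitted the depth for 27017 genes (89.0%).

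By the labels' protocols, RNA was extracted with the mirVana kit, samples with an RNA integrity number of at least 7 went on, and libraries were made with the TruSeq Stranded Total RNA kit. The submitters' processing notes name Trimmomatic for trimming and HISAT2 for alignment to GRCm39. Their versions, the counting tool, the annotation and the strand setting are not given in the sources used here, so genes that overlap or share sequence (Rnase4 with Ang, Acot1 with Acot2, the Sprr2a, Cyp2d and Aldh1a families, ribosomal proteins with their pseudogenes) are less certain than others. Symbols, lengths and GC content came from the GENCODE vM21 annotation of GRCm38, matched by gene identifier, which gave a symbol for 28734 genes (94.7%). No positions are given, since the builds differ.

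Because the values are FPKM, the plan's path for FPKM was used in place of the one for counts. Genes with a mean of at least 1 FPKM over the 9 libraries (11659) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a mean per group, a variance trend on the mean level and all 9 libraries in a single fit. P-values were two-sided and adjusted by Benjamini and Hochberg within each comparison, and 0.05 was the threshold. No count model was used for the main results. The groups, comparisons, threshold, filter, pseudocount, gene lists and alternatives were fixed before the data were examined, except that removing trends on GC content and length was added later. The comparison of directions with no NC library shared was also added after the data were seen. It set the mean of FFA_SIN against 1 NC library and took the changed genes from FFA against the other 2.

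In all, 30 gene lists were fixed in advance, 29 of which had tested members. They were tested with limma's camera at a preset correlation of 0.01, which compares a list with all other tested genes, with p-values adjusted over the 29 lists of each comparison. Lists count as changed at an adjusted p below 0.05: 18 for FFA against NC (12 up, 6 down), 14 for FFA_SIN against FFA (10 up, 4 down) and 17 for FFA_SIN against NC (13 up, 4 down). With the correlation estimated for each list, 9, 8 and 9 of these held. Members adjusted over the list alone used Benjamini and Hochberg within the list.

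Genes were named by a rule set in advance. Per comparison it took the 5 highest and the 5 lowest fold changes among changed genes with a proper symbol, at least 5 FPKM in the higher group and no overlap between libraries. It added up to 4 members with the smallest adjusted p in each list that passed or had 3 changed members, 22 lipid, stress, inflammation and hepatocyte genes always looked at, and the 5 opposite and 5 same-direction genes with the smallest larger adjusted p. The text names part of them, and results for some genes are not reported here. The 12 genes of the plot of FPKM per library were chosen after their values were seen.

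The fit was tried on simulated data with the means and spread of these libraries and 200 genes changed. For FFA against NC, 73.8% of genes changed 1.25-fold, 86.6% of those changed 1.5-fold and 97.0% of those changed 2-fold were found. For FFA_SIN against FFA the shares were 70.1%, 86.6% and 95.3%, and for FFA_SIN against NC 70.1%, 90.9% and 98.5%. Of unchanged genes 0.167%, 0.114% and 0.044% were called. In the data 31.2% to 51.3% of genes were called, far more than were changed in the simulation, so these shares need not hold there. Scripts ran in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.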

Results

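RNA was sequenced from AML12, a mouse hepatocyte cell line, in 3 groups of 3 libraries each: cells in standard medium (NC), cells given free fatty acids (FFA), and cells given free fatty acids and then free fatty acids together with sinomenine, a plant alkaloid, at 200 µM (FFA_SIN). By the series' design text, sinomenine came after 24 hours of fatty acids and stayed with them for 48 hours. How long the NC and FFA cultures ran is not stated, nor which fatty acids were used. The deposited table gave FPKM, fragments scaled to gene length and library depth, for 30350 genes. The read depth implied by its steps was 58862534 to 64460028 reads for NC, 43201346 to 67707660 for FFA, and 57912281 to 71391844 for FFA_SIN. At these depths a gene of 2000 bases with no reads could hold up to 0.0210 to 0.0347 FPKM, a limit that covers counting error only. In all, 11659 genes with a mean of at least 1 FPKM were tested.

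The libraries of each group lay close together. On the main axis of a principal component analysis, which held 61.3% of the variance, the FFA libraries (0.1 to 0.3) lay between NC (-17.7 to -16.8) and FFA_SIN (16.6 to 17.3). The next axis, with 14.3%, separated the FFA libraries (-10.5 to -8.5) from the NC and FFA_SIN libraries (4.4 to 4.95). Replicates were not copies of each other, since 0 pairs of libraries were identical and replicates differed beyond sampling noise (chi-square per gene 5.53 to 9.8 within groups, 41.7 to 139 between groups). Nothing in the labels says that replicates are separate cultures, so p-values measure only the spread between these libraries, which may be technical. Below, values are means ± SD in FPKM (n = 3 libraries per group), and log2FC is the log2 fold change ± SE on the log2(FPKM + 1) scale, which understates changes of low genes. Counts of changes of at least 2-fold are on the same scale and so leave out some low genes that moved 2-fold in FPKM.

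**Figure D1:**
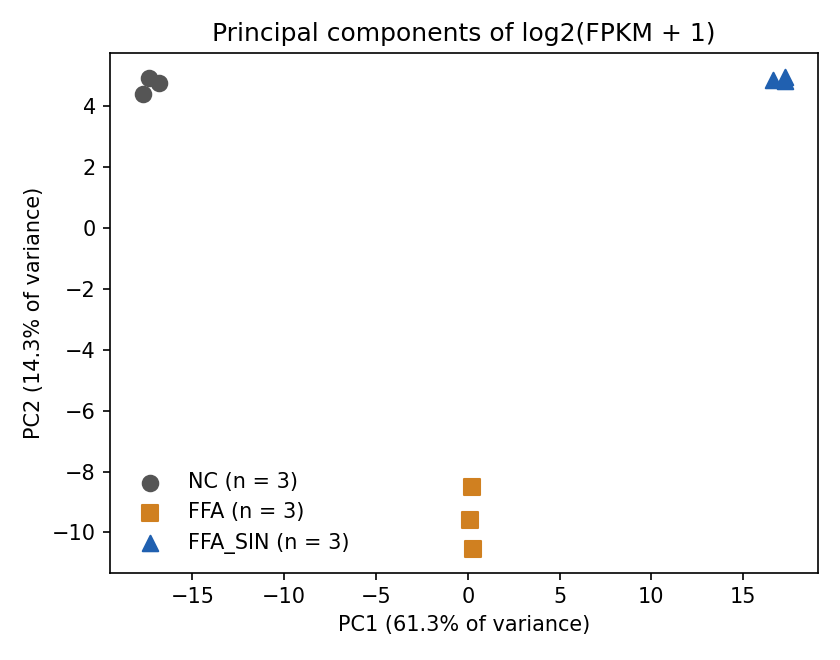
Principal components of log2(FPKM + 1) over the 11659 tested genes, with PC1 (61.3% of the variance) on the horizontal axis, PC2 (14.3%) on the vertical axis and each point a library. The FFA libraries sit between NC and FFA_SIN on PC1 and apart from both on PC2.

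Fatty acids raised genes of fatty acid oxidation, genes of lipid droplets and lipolysis, and nearly all genes of cholesterol synthesis. They lowered inflammatory genes, immediate early genes and genes of the unfolded protein response. FFA against NC holds the fatty acids together with any difference in culture time, since the durations of both cultures are not stated. The largest falls included the epithelial keratin Krt4 and the antibody transporter Pigr. Of the 11659 genes, 4369 (37.5%) changed between FFA and NC at an adjusted p below 0.05, 2228 up and 2141 down, and 52 of them changed at least 2-fold (17 up, 35 down). Without a filter on low values falls outnumbered rises instead (1864 up, 2003 down). They also did so, narrowly, with trends on GC content and length removed (2219 up, 2240 down). Most changes were small, with a median absolute log2FC of 0.19 among changed genes. The libraries of NC and FFA did not overlap for 5698 genes (48.9%), against 10% by chance.

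Of the genes of fatty acid oxidation and other PPAR alpha targets, 24 of 33 tested members rose and 1 fell (25 and 1 adjusted over the list alone). Tested by camera, the adjusted p was 2.85e-13 at a median log2FC of 0.22, or adjusted p = 0.00308 with an estimated correlation. Cpt1a, which admits fatty acids to mitochondria, rose from 37.2 ± 0.33 to 68.9 ± 1.32 FPKM (log2FC 0.87 ± 0.02, adjusted p = 6.6e-09). Acadl, which starts the breakdown of long-chain fatty acids inside them, rose from 67.1 ± 1.43 to 118 ± 1.07 FPKM (log2FC 0.81 ± 0.02, adjusted p = 1.6e-08). Acot1, a PPAR alpha target that releases fatty acids from coenzyme A and shares much of its sequence with Acot2, rose from 31.6 ± 0.921 to 91.9 ± 1.04 FPKM (log2FC 1.51 ± 0.03, adjusted p = 1.79e-09). Angptl4, a secreted inhibitor of lipoprotein lipase and another PPAR target, rose from 7.59 ± 0.278 to 11.4 ± 0.216 FPKM (log2FC 0.53 ± 0.04, adjusted p = 1.37e-05). Pdk4, which turns cells from glucose to fat as fuel, was too low to test, at 0 FPKM in all NC libraries and at most 0.0274 FPKM in any library.

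Of the genes of lipid droplets and lipolysis, 10 of 14 tested members rose and 2 fell (10 and 2 adjusted over the list alone). The median log2FC was 0.25 and the camera adjusted p was 0.000143, or adjusted p = 0.0273 with an estimated correlation. Plin2 (ENSMUSG00000028494), the main coat protein of droplets in hepatocytes, rose from 61.2 ± 0.301 to 161 ± 2.34 FPKM (log2FC 1.38 ± 0.02, adjusted p = 2.99e-10). Plin3, another coat protein, rose from 36.5 ± 0.306 to 46.5 ± 0.819 FPKM (log2FC 0.34 ± 0.03, adjusted p = 1.14e-05). Lipe, the hormone-sensitive lipase, rose from 2.22 ± 0.11 to 3.81 ± 0.0789 FPKM (log2FC 0.58 ± 0.04, adjusted p = 9.87e-06). Among genes of fatty acid uptake and binding, 6 of 9 tested members rose and 2 fell (6 and 2 adjusted over the list alone). At a median log2FC of 0.19, the camera adjusted p was 0.0212, or adjusted p = 0.135 with an estimated correlation. Without FFA replicate 3 the camera value was 0.0726. Cd36, a fatty acid transporter, rose from 1.98 ± 0.124 to 5.67 ± 0.294 FPKM (log2FC 1.16 ± 0.05, adjusted p = 2.4e-07). Cav1, the coat protein of caveolae, fell from 103 ± 1.64 to 88.6 ± 1.7 FPKM (log2FC -0.22 ± 0.02, adjusted p = 5.32e-05).

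Cholesterol synthesis showed the most uniform rise. Of the genes of this pathway and other SREBP2 targets, 26 of 28 tested members rose and 0 fell (26 and 0 adjusted over the list alone). Camera gave an adjusted p of 4.25e-20 at a median log2FC of 0.5, or adjusted p = 0.00308 with an estimated correlation. Insig1 (ENSMUSG00000045294), which holds the SREBP activator in the endoplasmic reticulum and is itself induced by it, rose from 8.85 ± 0.117 to 24.3 ± 0.862 FPKM (log2FC 1.36 ± 0.03, adjusted p = 3.34e-09). The pathway enzyme Fdps rose from 26.9 ± 0.729 to 66 ± 1.97 FPKM (log2FC 1.27 ± 0.03, adjusted p = 4.56e-09). Cyp51 and Msmo1, enzymes of its later steps, rose from 15.1 ± 0.47 to 38.8 ± 0.6 FPKM (adjusted p = 4.93e-09) and from 12.4 ± 0.0463 to 24.1 ± 0.0613 FPKM (adjusted p = 3.7e-09). Of the fatty acid and triglyceride synthesis genes, 16 of 25 tested members rose and 4 fell (17 and 4 adjusted over the list alone). Their median log2FC was 0.17 and the camera adjusted p 6.87e-05, or adjusted p = 0.106 with an estimated correlation. Fads1, a desaturase that makes polyunsaturated fatty acids, rose from 73.8 ± 1.28 to 111 ± 1.02 FPKM (log2FC 0.58 ± 0.02, adjusted p = 7.5e-08). Its partner Fads2 rose from 115 ± 3 to 162 ± 3.35 FPKM (adjusted p = 6.03e-07). Scd1, which makes monounsaturated ones, rose from 170 ± 2.75 to 193 ± 2.77 FPKM (log2FC 0.18 ± 0.02, adjusted p = 0.000135).

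Genes of the respiratory chain rose slightly with fatty acids, as lists at the preset correlation only (camera adjusted p = 0.143 for nuclear and 0.171 for mitochondrial genes with an estimated one). Of the nuclear-encoded oxidative phosphorylation genes, 31 of 44 tested members rose and 0 fell (32 and 0 adjusted over the list alone). By camera the adjusted p was 2.77e-08, or adjusted p = 0.143 with an estimated correlation, at a median log2FC of 0.16. The ATP synthase subunit Atp5b, for example, rose from 253 ± 2.8 to 290 ± 3.78 FPKM (log2FC 0.2 ± 0.02, adjusted p = 3.59e-05). Of the mitochondrially encoded genes, 8 of 13 tested members rose and 0 fell (8 and 0 adjusted over the list alone). For a median log2FC of 0.27, the camera adjusted p was 0.000625, or adjusted p = 0.171 with an estimated correlation. Mitochondrial transcripts, whose share also follows RNA handling, took 4.01 ± 0.08% of reads in NC, 4.54 ± 0.035% in FFA and 4.72 ± 0.209% in FFA_SIN. Among cytosolic ribosomal protein genes, 11 of 45 tested members rose and 0 fell (8 and 0 adjusted over the list alone). As a list these had a median log2FC of 0.07 and a camera adjusted p of 0.00367, or adjusted p = 0.538 with an estimated correlation. The camera value was 0.156 without NC replicate 2 and 0.0715 with trends on GC content and length removed. Of the lysosomal and autophagy genes, 23 of 45 tested members rose and 1 fell (25 and 1 adjusted over the list alone). Together they had a median log2FC of 0.12 and a camera adjusted p of 2.67e-08, or adjusted p = 0.00385 with an estimated correlation. Sqstm1, which hands cargo to autophagy, rose from 190 ± 0.451 to 239 ± 2.99 FPKM (log2FC 0.33 ± 0.02, adjusted p = 2.3e-06). Of the ferroptosis and iron genes, 17 of 26 tested members rose and 3 fell (17 and 4 adjusted over the list alone). Tested by camera, the adjusted p was 0.0012 at a median log2FC of 0.15, or adjusted p = 0.0299 with an estimated correlation. The iron carrier Trf rose from 474 ± 0.384 to 771 ± 8.21 FPKM (log2FC 0.7 ± 0.02, adjusted p = 6.6e-09).

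Inflammatory genes fell. Of the NF-kB and cytokine genes, 1 of 35 tested members rose and 22 fell (1 and 22 adjusted over the list alone). The median log2FC was -0.19 and the camera adjusted p was 4.51e-08, or adjusted p = 0.00405 with an estimated correlation. Nos2, the inducible nitric oxide synthase, fell from 16.4 ± 0.525 to 9.68 ± 0.443 FPKM (log2FC -0.71 ± 0.04, adjusted p = 8.61e-07). Ptgs2, which makes prostaglandins, fell from 12.5 ± 0.0894 to 6.77 ± 0.26 FPKM (log2FC -0.8 ± 0.04, adjusted p = 6.89e-07). Ccl2, which draws in monocytes, fell from 451 ± 20.1 to 331 ± 11.7 FPKM (log2FC -0.44 ± 0.04, adjusted p = 2.39e-05). The neutrophil attractant Cxcl1 fell from 181 ± 2.69 to 156 ± 5.08 FPKM (log2FC -0.21 ± 0.03, adjusted p = 0.000574). Tnf fell from 3.02 ± 0.379 to 1.99 ± 0.182 FPKM (log2FC -0.42 ± 0.08, adjusted p = 0.00269). Il6 was too low to test, with at most 0.0769 FPKM in any library. The immediate early genes, which respond to growth signals within minutes, fell as well. Of this list, 1 of 23 tested members rose and 18 fell (1 and 20 adjusted over the list alone). At a median log2FC of -0.3, the camera adjusted p was 1.94e-08, or adjusted p = 0.0446 with an estimated correlation. Egr1 fell from 20 ± 1.1 to 12.1 ± 0.721 FPKM (log2FC -0.68 ± 0.05, adjusted p = 6.33e-06). Myc fell from 57.6 ± 0.524 to 37.7 ± 0.482 FPKM (log2FC -0.6 ± 0.03, adjusted p = 2.85e-07).

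Stress pathways split. In the unfolded protein response of the endoplasmic reticulum (ER), 2 of 29 tested members rose and 13 fell (2 and 14 adjusted over the list alone). Camera gave an adjusted p of 0.00102 at a median log2FC of -0.09, or adjusted p = 0.0298 with an estimated correlation. Its chaperone Hspa5 (ENSMUSG00000026864) fell from 228 ± 2.1 to 176 ± 1.49 FPKM (log2FC -0.37 ± 0.02, adjusted p = 3.96e-07). In the integrated stress response under the factor ATF4, which includes amino acid synthesis, more genes rose than fell. Of its list, 17 of 32 tested members rose and 5 fell (19 and 7 adjusted over the list alone). Their median log2FC was 0.14 and the camera adjusted p 0.0014, or adjusted p = 0.135 with an estimated correlation. Asns, which makes asparagine, rose from 34.5 ± 0.104 to 56.4 ± 1 FPKM (log2FC 0.7 ± 0.02, adjusted p = 5.46e-08). Psat1, which makes serine, rose from 89.5 ± 2.23 to 133 ± 3.04 FPKM (log2FC 0.57 ± 0.03, adjusted p = 3.67e-07). The factor Ddit3, known for cell death under ER stress, did not differ (log2FC -0.01 ± 0.04, adjusted p = 0.89). Of the p53 targets and apoptosis genes, 4 of 34 tested members rose and 16 fell (4 and 17 adjusted over the list alone). By camera the adjusted p was 0.000874, or adjusted p = 0.0294 with an estimated correlation, at a median log2FC of -0.08. Mdm2, which degrades p53 and is induced by it, fell from 38 ± 0.664 to 26.6 ± 0.256 FPKM (log2FC -0.5 ± 0.02, adjusted p = 3.05e-07). Of the circadian clock genes, 1 of 14 tested members rose and 9 fell (1 and 9 adjusted over the list alone). For a median log2FC of -0.16, the camera adjusted p was 0.000387, or adjusted p = 0.108 with an estimated correlation. Per2 was among the falls (log2FC -0.44 ± 0.03, adjusted p = 2.3e-06). Clock genes also follow serum and time of harvest, and immediate early genes follow serum, so neither fall can be tied to fatty acids alone.

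The 5 largest falls among well-expressed genes were in Krt4, Sprr2a3, Pigr, Sult1a1 and Ltf. Krt4 (ENSMUSG00000059668), a keratin of squamous epithelia, fell from 55.7 ± 0.676 to 4.65 ± 0.527 FPKM (log2FC -3.33 ± 0.07, adjusted p = 4.93e-09). Pigr (ENSMUSG00000026417), which carries antibodies across epithelia, fell from 48.3 ± 0.851 to 8.54 ± 0.236 FPKM (log2FC -2.37 ± 0.03, adjusted p = 1.86e-10). Ltf, the iron-binding protein of secretions, fell from 30.9 ± 0.287 to 9.46 ± 0.258 FPKM (log2FC -1.61 ± 0.05, adjusted p = 6.02e-08). Sult1a1, which attaches sulfate to phenols and drugs, fell from 41 ± 0.788 to 10.5 ± 0.14 FPKM (log2FC -1.87 ± 0.03, adjusted p = 1.11e-09). Sprr2a3, a cell envelope gene with near-identical copies whose reads may be shared, fell from 8.58 ± 0.534 to 0.747 ± 0.0693 FPKM (log2FC -2.45 ± 0.06, adjusted p = 8.22e-09). Besides lipid genes, Depp1, a target of FOXO factors in fasting, was among the 5 largest rises, from 2.16 ± 0.294 to 9.14 ± 0.626 FPKM (log2FC 1.68 ± 0.07, adjusted p = 1.94e-07).

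Antioxidant genes under NRF2 moved both ways in FFA against NC. Of the list, 10 of 38 tested members rose and 18 fell (10 and 19 adjusted over the list alone). As a list these had a median log2FC of -0.07 and a camera adjusted p of 0.0493, or adjusted p = 0.108 with an estimated correlation. The call lay at the threshold and was lost in other settings, since the camera adjusted p was 0.051 with median-of-ratios size factors and 0.0521 with replicate number as a block. It was 0.0549 without NC replicate 1, 0.0553 without NC replicate 3 and 0.0557 without FFA replicate 2. Camera gave 0.0539 without FFA replicate 3, 0.0527 without FFA_SIN replicate 1 and 0.0546 without FFA_SIN replicate 3. Within it the glutathione transferase Gstm1 fell from 784 ± 10.4 to 513 ± 9.39 FPKM (log2FC -0.61 ± 0.02, adjusted p = 8.68e-08). Hmox1, which breaks down heme, rose from 24.9 ± 0.994 to 39.2 ± 1.5 FPKM (log2FC 0.63 ± 0.04, adjusted p = 4.97e-06). Nqo1 was below the filter, at 0.721 ± 0.211 FPKM in NC. Of the replication-dependent histones, 5 of 11 tested members rose and 0 fell (6 and 0 adjusted over the list alone). Together they had a median log2FC of 0.22 and a camera adjusted p of 0.0265, or adjusted p = 0.171 with an estimated correlation. The camera value was 0.0685 without NC replicate 2.

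The other lists did not pass as groups. Hepatocyte identity genes went both ways (9 rose and 6 fell of 22 (9 and 6 adjusted over the list alone; camera adjusted p = 0.467)). Alb, the main plasma protein, rose from 198 ± 1.03 to 271 ± 0.631 FPKM (log2FC 0.46 ± 0.02, adjusted p = 7.5e-08). The liver transcription factor Hnf4a fell from 131 ± 0.556 to 118 ± 1.71 FPKM (log2FC -0.16 ± 0.02, adjusted p = 0.000169). Cell cycle genes also split (19 rose and 15 fell of 47 (21 and 15 adjusted over the list alone; camera adjusted p = 0.559)). So did genes of glycolysis and hypoxia (13 rose and 5 fell of 32 (14 and 5 adjusted over the list alone; camera adjusted p = 0.181)). Xenobiotic metabolism genes had no common direction (6 rose and 5 fell of 18 (6 and 5 adjusted over the list alone; camera adjusted p = 0.837)). The list's median log2FC was 0.06, its mean -0.17 and the test pointed down. Acute phase genes were not past the threshold (4 rose and 2 fell of 15 (5 and 2 adjusted over the list alone; camera adjusted p = 0.23)). Neither were matrix and YAP target genes (4 rose and 7 fell of 25 (4 and 7 adjusted over the list alone; camera adjusted p = 0.163)). The same held for lipoprotein genes (2 rose and 2 fell of 10 (2 and 2 adjusted over the list alone; camera adjusted p = 0.796)). Interferon-stimulated genes did not pass either (2 rose and 3 fell of 15 (2 and 3 adjusted over the list alone; camera adjusted p = 0.796)).

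Markers of other liver cell types were low or did not move as groups with fatty acids. Cholangiocyte markers split (1 rose and 3 fell of 7 (2 and 3 adjusted over the list alone; camera adjusted p = 0.306)). They were not all low, with Krt19 at 1352 ± 33.1 FPKM in NC and 1258 ± 9.57 in FFA (log2FC -0.1 ± 0.02, adjusted p = 0.00644). The markers' median log2FC was 0.02, their mean -0.13 and the test pointed down. Macrophage markers did not pass (0 rose and 2 fell of 3 (0 and 2 adjusted over the list alone; camera adjusted p = 0.121)). The only tested stellate cell marker, Des, fell (log2FC -0.66 ± 0.05, adjusted p = 8.55e-06). With 0 risen and 1 fallen, also when adjusted over the list alone, its list had a camera adjusted p of 0.0525, and of 0.0397 without FFA replicate 1, 0.0327 without FFA replicate 3 and 0.0327 by limma-voom on recovered reads. Of the endothelial markers, 0 were high enough to test. The model was limma's, with p-values adjusted by Benjamini and Hochberg over all tested genes. With 3 libraries against 3, an exact permutation test of a single gene could not give a p below 0.1.

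Sinomenine, added on top of fatty acids, raised genes of the integrated stress response, of the unfolded protein response, of glycolysis and hypoxia and of the acute phase. It lowered genes of xenobiotic metabolism and of the cell cycle. Inflammatory genes fell more often than they rose (19 and 7 of 35), a list not past the threshold with an estimated correlation (camera adjusted p = 0.0564). The lipid droplet coat Plin2, raised by fatty acids, rose further. Between FFA_SIN and FFA, 3638 genes (31.2%) changed, 1620 up and 2018 down, and 63 of them at least 2-fold (27 up, 36 down). The balance depended on the scaling, with 1871 up and 1760 down under median-of-ratios size factors. The median absolute log2FC among them was 0.19, and the libraries did not overlap for 5306 genes (45.5%), against 10% by chance.

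The response under ATF4 showed the most uniform rise with sinomenine. Of its genes, 25 of 32 tested members rose and 0 fell (27 and 0 adjusted over the list alone). Tested by camera, the adjusted p was 7.78e-14 at a median log2FC of 0.22, or adjusted p = 0.0125 with an estimated correlation. Ddit3 (ENSMUSG00000025408) rose from 4.56 ± 0.131 to 14.2 ± 0.628 FPKM (log2FC 1.45 ± 0.04, adjusted p = 3.74e-08). Trib3, a pseudokinase induced by ATF4 and Ddit3 that dampens insulin signalling, rose from 19.1 ± 0.319 to 33.5 ± 0.647 FPKM (log2FC 0.78 ± 0.04, adjusted p = 6.07e-07). The stress factor Atf3 rose from 5.43 ± 0.237 to 10.7 ± 0.133 FPKM (log2FC 0.86 ± 0.04, adjusted p = 5.7e-07). Slc3a2, a subunit of amino acid transporters, rose from 108 ± 1.93 to 168 ± 2.65 FPKM (log2FC 0.63 ± 0.02, adjusted p = 6.65e-08). Of the unfolded protein response genes, 17 of 29 tested members rose and 2 fell (20 and 2 adjusted over the list alone). The median log2FC was 0.14 and the camera adjusted p was 1.15e-08, or adjusted p = 0.00645 with an estimated correlation. The chaperone Hspa5 rose from 176 ± 1.49 to 254 ± 1.39 FPKM (log2FC 0.53 ± 0.02, adjusted p = 4.43e-08). Hsp90b1 and Hyou1, further ER chaperones, rose from 102 ± 1.79 to 132 ± 3.14 FPKM (adjusted p = 3.32e-06) and from 15.3 ± 0.339 to 21.4 ± 0.6 FPKM (adjusted p = 4.34e-06). Xbp1, a transcription factor of the same response, fell from 74 ± 0.784 to 56.7 ± 0.999 FPKM (log2FC -0.38 ± 0.02, adjusted p = 1.19e-06).

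Of the genes of glycolysis and hypoxia, 24 of 32 tested members rose and 5 fell (25 and 5 adjusted over the list alone). At a median log2FC of 0.32, the camera adjusted p was 6.85e-12, or adjusted p = 0.00645 with an estimated correlation. Bnip3 (ENSMUSG00000078566), a hypoxia target that marks mitochondria for removal, rose from 16.3 ± 0.629 to 36.8 ± 0.702 FPKM (log2FC 1.13 ± 0.03, adjusted p = 3.74e-08). Ndrg1, another hypoxia target, rose from 38.7 ± 0.674 to 61.3 ± 0.294 FPKM (log2FC 0.65 ± 0.02, adjusted p = 1.09e-07). P4ha2, which hydroxylates collagen, rose from 7.34 ± 0.0722 to 11.7 ± 0.211 FPKM (log2FC 0.61 ± 0.03, adjusted p = 3.46e-07). Pdk1 rose from 9.45 ± 0.124 to 14 ± 0.3 FPKM (log2FC 0.52 ± 0.03, adjusted p = 8.67e-07). The glucose transporter Slc2a1, which had fallen with fatty acids, rose from 23.1 ± 0.465 to 29.9 ± 0.755 FPKM (log2FC 0.36 ± 0.03, adjusted p = 1.1e-05). Lysosomal and autophagy genes rose again. Among them, 25 of 45 tested members rose and 1 fell (25 and 1 adjusted over the list alone). Camera gave an adjusted p of 1.47e-09 at a median log2FC of 0.16, or adjusted p = 0.00645 with an estimated correlation. Hexa and Neu1, enzymes that strip sugars in lysosomes, rose from 34.6 ± 0.656 to 47 ± 0.585 FPKM (adjusted p = 3.79e-06) and from 29.8 ± 0.634 to 40.9 ± 0.476 FPKM (adjusted p = 4.81e-06). Sqstm1 rose from 239 ± 2.99 to 290 ± 5.65 FPKM (log2FC 0.28 ± 0.02, adjusted p = 6.88e-06).

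Of the acute phase genes, 9 of 15 tested members rose and 1 fell (9 and 1 adjusted over the list alone). Their median log2FC was 0.37 and the camera adjusted p 7.48e-06, or adjusted p = 0.0125 with an estimated correlation. Hp, which binds free hemoglobin, rose from 10.5 ± 0.322 to 24 ± 0.725 FPKM (log2FC 1.13 ± 0.04, adjusted p = 4.43e-08). Cp, the copper-carrying ferroxidase, rose from 107 ± 1.23 to 181 ± 5.14 FPKM (log2FC 0.76 ± 0.02, adjusted p = 3.93e-08). The acute phase protein Saa3 rose from 4.35 ± 0.324 to 17.9 ± 0.289 FPKM (log2FC 1.82 ± 0.07, adjusted p = 1.87e-07). Fgb, a chain of fibrinogen, rose from 2.24 ± 0.118 to 5.57 ± 0.332 FPKM (log2FC 1.02 ± 0.05, adjusted p = 5.3e-07). Lbp, which binds bacterial lipopolysaccharide, fell from 397 ± 2.27 to 325 ± 4.23 FPKM (log2FC -0.29 ± 0.02, adjusted p = 5.94e-06). Hepatocyte identity genes as a group went both ways (7 rose and 9 fell of 22 (7 and 9 adjusted over the list alone; camera adjusted p = 0.679)). Within them Alb (ENSMUSG00000029368) rose from 271 ± 0.631 to 556 ± 3.47 FPKM (log2FC 1.03 ± 0.02, adjusted p = 8.7e-10). Rbp4, the carrier of retinol, rose from 122 ± 1.98 to 191 ± 4.06 FPKM (log2FC 0.64 ± 0.03, adjusted p = 2.93e-07). Hnf4a fell from 118 ± 1.71 to 104 ± 1.16 FPKM (log2FC -0.18 ± 0.02, adjusted p = 8.14e-05).

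Xenobiotic metabolism genes fell. Of the list, 3 of 18 tested members rose and 14 fell (3 and 14 adjusted over the list alone). By camera the adjusted p was 4.46e-06, or adjusted p = 0.032 with an estimated correlation, at a median log2FC of -0.47. The cytochrome Cyp2d10, from a family of near-identical genes, fell from 9.34 ± 0.296 to 3.99 ± 0.21 FPKM (log2FC -1.05 ± 0.04, adjusted p = 8.83e-08). The oxygenase Fmo1 and the glucuronosyltransferase Ugt2b34 fell from 15.5 ± 0.322 to 9.96 ± 0.31 FPKM (adjusted p = 1.23e-06) and from 207 ± 0.995 to 146 ± 5.51 FPKM (adjusted p = 1.47e-06). Sult1a1 fell from 10.5 ± 0.14 to 5.84 ± 0.255 FPKM (log2FC -0.75 ± 0.03, adjusted p = 2.44e-07). Cell cycle genes fell slightly. Among these, 1 of 47 tested members rose and 19 fell (1 and 20 adjusted over the list alone). For a median log2FC of -0.09, the camera adjusted p was 0.000681, or adjusted p = 0.0188 with an estimated correlation. The proliferation marker Mki67 fell from 23.9 ± 0.414 to 20.8 ± 0.422 FPKM (log2FC -0.19 ± 0.03, adjusted p = 0.000739). Ccna2, the cyclin of DNA replication, fell from 18.6 ± 0.439 to 16.1 ± 0.294 FPKM (log2FC -0.19 ± 0.02, adjusted p = 0.000306). Of the p53 targets and apoptosis genes, 16 of 34 tested members rose and 0 fell (17 and 1 adjusted over the list alone). As a list these had a median log2FC of 0.09 and a camera adjusted p of 0.000912, or adjusted p = 0.023 with an estimated correlation. The cell cycle inhibitor Cdkn1a rose from 50.1 ± 1.79 to 63.5 ± 1.44 FPKM (log2FC 0.34 ± 0.03, adjusted p = 2.66e-05).

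Inflammatory genes went both ways with more falls. Of these, 7 of 35 tested members rose and 19 fell (7 and 19 adjusted over the list alone). Together they had a median log2FC of -0.13 and a camera adjusted p of 0.0164, or adjusted p = 0.0564 with an estimated correlation. Tnfaip2 fell from 17 ± 0.371 to 8.28 ± 0.243 FPKM (log2FC -0.95 ± 0.03, adjusted p = 3.18e-08). Nfkbiz, a cofactor of NF-kB, fell from 38.5 ± 0.975 to 22.9 ± 0.657 FPKM (log2FC -0.72 ± 0.03, adjusted p = 2.36e-07). Gsdmd, the pore former of pyroptosis, fell from 150 ± 2.02 to 114 ± 1.16 FPKM (log2FC -0.39 ± 0.02, adjusted p = 7.81e-07). Tnf and Cxcl1 fell from 1.99 ± 0.182 to 0.879 ± 0.108 FPKM (adjusted p = 0.000196) and from 156 ± 5.08 to 128 ± 3.94 FPKM (adjusted p = 9.89e-05). Ccl2 instead rose from 331 ± 11.7 to 543 ± 13.8 FPKM (log2FC 0.71 ± 0.04, adjusted p = 1.22e-06), above its level in NC. Of the matrix, TGF beta and YAP target genes, 11 of 25 tested members rose and 6 fell (11 and 7 adjusted over the list alone). Tested by camera, the adjusted p was 0.00983 at a median log2FC of 0.05, or adjusted p = 0.0529 with an estimated correlation. Fn1, fibronectin, fell from 35.8 ± 0.637 to 21.1 ± 0.334 FPKM (log2FC -0.74 ± 0.03, adjusted p = 1.7e-07). It had not changed with fatty acids (log2FC -0.03 ± 0.03, adjusted p = 0.395).

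Lipid genes did not move as a block with sinomenine. Fatty acid oxidation genes did not pass (4 rose and 11 fell of 33 (6 and 13 adjusted over the list alone; camera adjusted p = 0.115)). Ppargc1a, a coactivator of mitochondrial genes, rose from 1.51 ± 0.0397 to 2.56 ± 0.0539 FPKM (log2FC 0.5 ± 0.04, adjusted p = 2.07e-05). Cpt1a was not past the threshold (log2FC -0.03 ± 0.02, adjusted p = 0.256). Cholesterol genes split (8 rose and 11 fell of 28 (9 and 11 adjusted over the list alone; camera adjusted p = 0.516)). Insig1 rose from 24.3 ± 0.862 to 30.3 ± 0.0895 FPKM (adjusted p = 2.77e-05). Of the lipid droplet genes, 6 of 14 tested members rose and 2 fell (8 and 2 adjusted over the list alone). The median log2FC was 0.08 and the camera adjusted p was 0.0153, or adjusted p = 0.0607 with an estimated correlation. Plin2 rose from 161 ± 2.34 to 192 ± 2.92 FPKM (log2FC 0.26 ± 0.02, adjusted p = 9.66e-06). Hsd17b13, a droplet enzyme tied to fatty liver disease, rose from 4.2 ± 0.443 to 11.8 ± 0.175 FPKM (log2FC 1.31 ± 0.05, adjusted p = 2.31e-07). Fatty acid and triglyceride synthesis genes did not pass (4 rose and 9 fell of 25 (4 and 9 adjusted over the list alone; camera adjusted p = 0.429)). Nor did uptake genes (1 rose and 4 fell of 9 (1 and 4 adjusted over the list alone; camera adjusted p = 0.197)), though Cd36 fell from 5.67 ± 0.294 to 3.82 ± 0.167 FPKM (adjusted p = 8e-05). Lipoprotein genes did not pass (1 rose and 4 fell of 10 (1 and 4 adjusted over the list alone; camera adjusted p = 0.367)).

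Antioxidant genes went both ways with sinomenine and did not pass as a group (10 rose and 14 fell of 38 (11 and 17 adjusted over the list alone; camera adjusted p = 0.627)). The group's median log2FC was -0.05, its mean 0.01 and the test pointed down. Osgin1, a growth inhibitor under oxidative stress, rose from 159 ± 5.5 to 337 ± 6.08 FPKM (log2FC 1.08 ± 0.03, adjusted p = 2.37e-08). Hmox1 rose from 39.2 ± 1.5 to 80.7 ± 3.75 FPKM (log2FC 1.02 ± 0.04, adjusted p = 2.36e-07). Cat, which breaks down hydrogen peroxide, rose from 205 ± 2.27 to 268 ± 1.87 FPKM (log2FC 0.39 ± 0.02, adjusted p = 8.37e-07). Among the falls, Gstm1 went from 513 ± 9.39 to 429 ± 7.14 FPKM (log2FC -0.26 ± 0.02, adjusted p = 2.01e-05). Gsta4 went from 322 ± 3.74 to 289 ± 3.2 FPKM (log2FC -0.16 ± 0.02, adjusted p = 0.000604). Of the ferroptosis and iron genes, 11 of 26 tested members rose and 3 fell (12 and 3 adjusted over the list alone). At a median log2FC of 0.02, the camera adjusted p was 0.0175, or adjusted p = 0.0607 with an estimated correlation. The iron exporter Slc40a1 rose from 13.2 ± 0.132 to 17 ± 0.591 FPKM (log2FC 0.34 ± 0.03, adjusted p = 2.85e-05).

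The 5 largest rises among well-expressed genes with sinomenine were in Rnase4, Fabp6, Ang, Saa3 and Ddit3. Rnase4 (ENSMUSG00000021876) rose from 5.54 ± 0.683 to 49.7 ± 0.496 FPKM (log2FC 2.96 ± 0.07, adjusted p = 8.3e-09). Ang, which shares its promoters and first exons, rose from 1.12 ± 0.189 to 7.25 ± 0.612 FPKM (log2FC 1.96 ± 0.09, adjusted p = 3.53e-07), so reads of the pair may be shared. Fabp6 (ENSMUSG00000020405), which binds bile acids in the gut, was listed at 0 in all NC and FFA libraries and at 6.40, 4.11 and 4.50 FPKM in FFA_SIN replicates 1 to 3.

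Among well-expressed genes, the 5 largest falls with sinomenine were in Scgb3a1, S100a9, Duoxa1, Ms4a8a and Olfm4. Scgb3a1, a secretoglobin of airway lining, fell from 13.5 ± 1.15 to 1.79 ± 0.635 FPKM (log2FC -2.4 ± 0.14, adjusted p = 1.88e-06). S100a9, a subunit of neutrophil calprotectin, fell from 11.7 ± 0.399 to 2.23 ± 0.291 FPKM (log2FC -1.98 ± 0.1, adjusted p = 6.17e-07). Duoxa1, which matures a peroxide-making oxidase, fell from 12.6 ± 0.445 to 3.15 ± 0.325 FPKM (log2FC -1.72 ± 0.05, adjusted p = 4.18e-08). Ms4a8a, a membrane protein of ciliated and myeloid cells, fell from 13.8 ± 0.483 to 3.65 ± 0.19 FPKM (log2FC -1.67 ± 0.04, adjusted p = 8.3e-09). Olfm4, known from gut stem cells, fell from 108 ± 2.32 to 33.5 ± 0.291 FPKM (log2FC -1.65 ± 0.02, adjusted p = 8.7e-10). Except for S100a9 (log2FC -0.25 ± 0.1, adjusted p = 0.0668), each of them had already fallen with fatty acids.

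The remaining lists did not move as groups with sinomenine. Oxidative phosphorylation genes stayed level (2 rose and 4 fell of 44 (1 and 3 adjusted over the list alone; camera adjusted p = 0.986)). Mitochondrially encoded genes did not pass (5 rose and 0 fell of 13 (5 and 0 adjusted over the list alone; camera adjusted p = 0.121)), but had an adjusted p of 0.0145 without FFA_SIN replicate 3. Interferon-stimulated genes (5 rose and 2 fell of 15 (5 and 3 adjusted over the list alone; camera adjusted p = 0.327)) did not pass. Nor did clock genes (3 rose and 2 fell of 14 (3 and 2 adjusted over the list alone; camera adjusted p = 0.549)). Histones did not pass (2 rose and 1 fell of 11 (2 and 1 adjusted over the list alone; camera adjusted p = 0.911)), with a median and mean log2FC of -0.09 and the test pointing up. Immediate early genes did not pass either (5 rose and 5 fell of 23 (6 and 8 adjusted over the list alone; camera adjusted p = 0.948)), with a median log2FC of -0.01, a mean of -0.005 and the test pointing up.

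For cytosolic ribosomal proteins with sinomenine, 1 of 45 tested members rose and 1 fell (0 and 0 adjusted over the list alone). Camera gave an adjusted p of 0.0494 at a median log2FC of 0.04, or adjusted p = 0.699 with an estimated correlation. The camera value was 0.304 without FFA replicate 2, 0.0873 without FFA_SIN replicate 1 and 0.128 without FFA_SIN replicate 3. The stellate cell marker Des fell (log2FC -0.79 ± 0.05, adjusted p = 2.92e-06). Its list of 1 tested member, with 0 risen and 1 fallen also when adjusted over the list alone, had a camera adjusted p of 0.0494, and adjusted p = 0.144 with an estimated correlation. Camera gave 0.0601, 0.0621 and 0.059 without NC replicates 1, 2 and 3. It gave 0.0593 without FFA replicate 2, and 0.0523, 0.0509 and 0.0581 without FFA_SIN replicates 1, 2 and 3. With replicate number as a block it was 0.0596, and with trends on GC content and length removed 0.062. Macrophage markers did not pass (0 rose and 2 fell of 3 (0 and 2 adjusted over the list alone; camera adjusted p = 0.151)). Cholangiocyte markers did not either (3 rose and 2 fell of 7 (3 and 2 adjusted over the list alone; camera adjusted p = 0.531)). Because the durations of the NC and FFA cultures are not stated, this comparison holds sinomenine and any difference in culture time together.

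**Figure D2:**
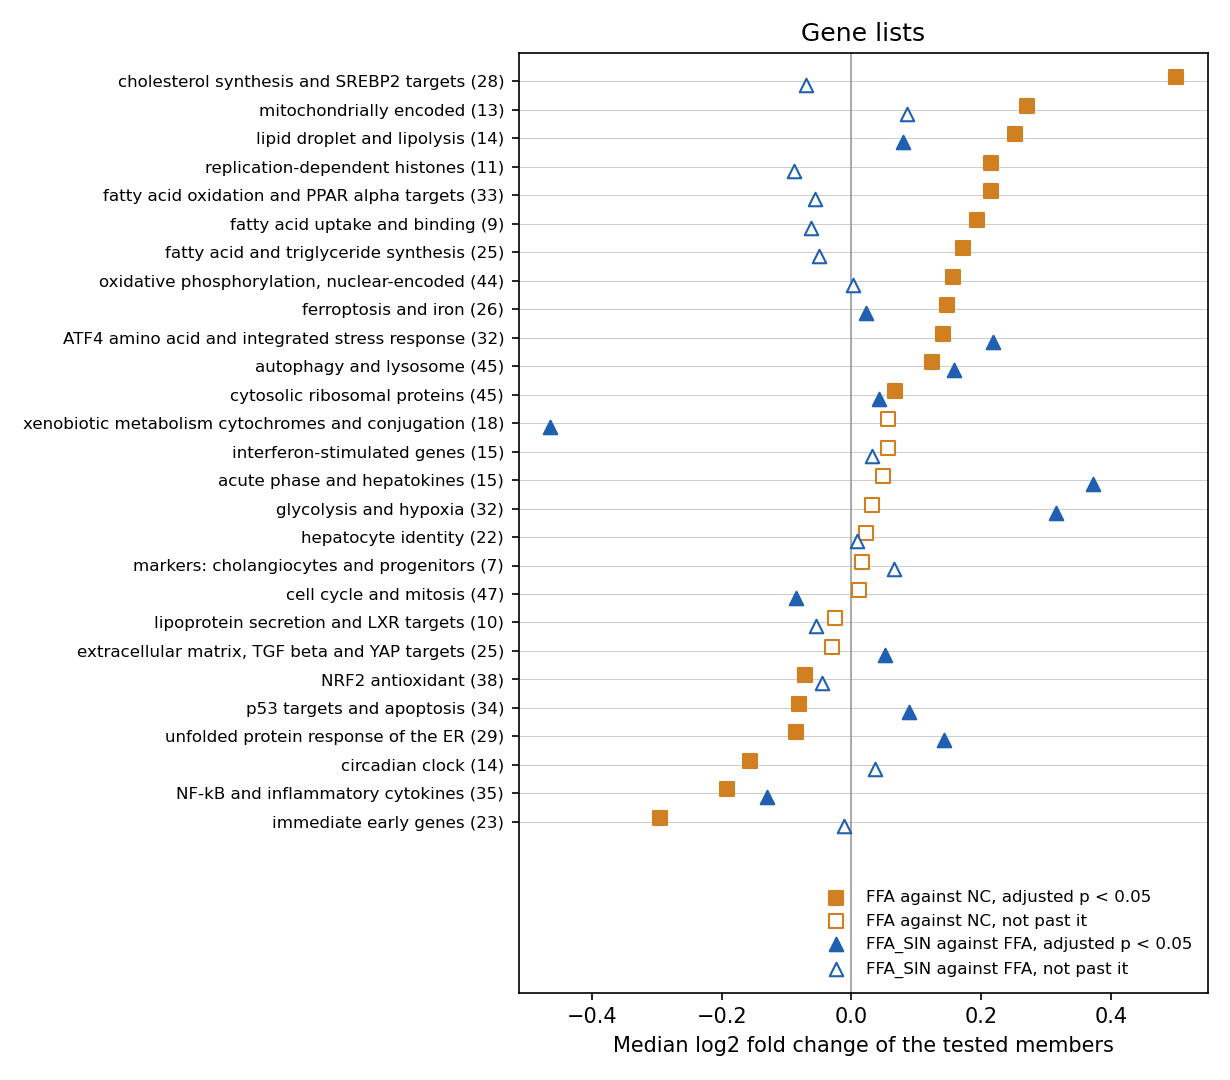
Median log2FC of the tested members of each gene list with at least 5 of them (number in brackets), for FFA against NC (squares) and FFA_SIN against FFA (triangles), filled where the camera adjusted p was below 0.05. Cholesterol synthesis had the highest median with fatty acids (0.50), and acute phase genes the highest with sinomenine (0.37).

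Set against untreated cells, cells with fatty acids and sinomenine kept the direction of most fatty acid changes (89.4% to 90.3% with no NC library shared between the comparisons, against at most 50.1% if independent). Cholesterol synthesis and fatty acid oxidation stayed up, inflammatory genes stayed down, and genes of the integrated stress response and hypoxia stood higher. Between FFA_SIN and NC, 5977 genes (51.3%) changed, 2883 up and 3094 down, against 3116 up and 2842 down under median-of-ratios size factors. With trends on GC content and length removed, 3085 rose and 3082 fell. Of the 5977, 188 changed at least 2-fold (61 up, 127 down), with a median absolute log2FC of 0.22. The libraries did not overlap for 7004 genes (60.1%), against 10% by chance. The 5 largest rises among well-expressed genes were in Rnase4, Depp1, Fabp6, Ang and Hp, and the 5 largest falls in Krt4, Scgb3a1, Pigr, Ltf and Duoxa1.

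In lipid metabolism, fatty acid oxidation genes were higher in FFA_SIN than in NC. Of these, 25 of 33 tested members rose and 1 fell (26 and 1 adjusted over the list alone). Camera gave an adjusted p of 3.02e-08 at a median log2FC of 0.2, or adjusted p = 0.0086 with an estimated correlation. Cpt1a stood at 67.3 ± 0.775 FPKM (log2FC 0.84 ± 0.02, adjusted p = 2.41e-09). Of the cholesterol genes, 25 of 28 tested members rose and 1 fell (25 and 1 adjusted over the list alone). Their median log2FC was 0.51 and the camera adjusted p 1.31e-12, or adjusted p = 0.00589 with an estimated correlation. Insig1 rose from 8.85 ± 0.117 to 30.3 ± 0.0895 FPKM (log2FC 1.67 ± 0.03, adjusted p = 2.52e-10). Of the lipid droplet genes, 9 of 14 tested members rose and 1 fell (9 and 1 adjusted over the list alone). By camera the adjusted p was 0.000186, or adjusted p = 0.0228 with an estimated correlation, at a median log2FC of 0.4. Plin2 rose from 61.2 ± 0.301 to 192 ± 2.92 FPKM (log2FC 1.64 ± 0.02, adjusted p = 3.54e-11). Of the fatty acid and triglyceride synthesis genes, 15 of 25 tested members rose and 4 fell (15 and 4 adjusted over the list alone). Their median log2FC was 0.14 and the camera adjusted p 0.0022, or adjusted p = 0.173 with an estimated correlation. Lpin2, which makes diacylglycerol, rose from 6.18 ± 0.188 to 10.6 ± 0.0571 FPKM (log2FC 0.69 ± 0.03, adjusted p = 7.67e-08). Uptake genes did not pass (5 rose and 2 fell of 9 (6 and 2 adjusted over the list alone; camera adjusted p = 0.111)), although Cav1 fell (log2FC -0.42 ± 0.02, adjusted p = 2.59e-07). Lipoprotein genes did not pass either (3 rose and 5 fell of 10 (3 and 5 adjusted over the list alone; camera adjusted p = 0.416)), although Abcg5, a sterol exporter, fell (log2FC -0.45 ± 0.07, adjusted p = 0.000728).

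Genes of the integrated stress response were higher too. Of the ATF4 genes, 24 of 32 tested members rose and 4 fell (25 and 4 adjusted over the list alone). For a median log2FC of 0.42, the camera adjusted p was 1.69e-09, or adjusted p = 0.0228 with an estimated correlation. Asns and Trib3 rose from 34.5 ± 0.104 to 66.1 ± 1.36 FPKM (adjusted p = 2.07e-09) and from 14.4 ± 0.817 to 33.5 ± 0.647 FPKM (adjusted p = 1.35e-08). Of the unfolded protein response genes, 15 of 29 tested members rose and 5 fell (15 and 6 adjusted over the list alone). By camera the adjusted p was 0.0184, or adjusted p = 0.0784 with an estimated correlation, at a median log2FC of 0.1. The chaperone Dnajc10 rose from 74.8 ± 1.52 to 115 ± 1.51 FPKM (log2FC 0.62 ± 0.02, adjusted p = 1.52e-08). Of the autophagy and lysosome genes, 32 of 45 tested members rose and 2 fell (32 and 2 adjusted over the list alone). As a list these had a median log2FC of 0.25 and a camera adjusted p of 2.46e-10, or adjusted p = 0.00559 with an estimated correlation. Sqstm1 rose from 190 ± 0.451 to 290 ± 5.65 FPKM (log2FC 0.61 ± 0.02, adjusted p = 1.41e-08). Of the glycolysis and hypoxia genes, 23 of 32 tested members rose and 4 fell (23 and 5 adjusted over the list alone). Together they had a median log2FC of 0.33 and a camera adjusted p of 2.55e-07, or adjusted p = 0.0163 with an estimated correlation. Bnip3 rose from 12.4 ± 0.427 to 36.8 ± 0.702 FPKM (log2FC 1.49 ± 0.03, adjusted p = 1.63e-09). Of the ferroptosis and iron genes, 16 of 26 tested members rose and 4 fell (16 and 4 adjusted over the list alone). For a median log2FC of 0.12, the camera adjusted p was 0.00146, or adjusted p = 0.0293 with an estimated correlation. Trf rose from 474 ± 0.384 to 1019 ± 5.88 FPKM (log2FC 1.1 ± 0.02, adjusted p = 1.9e-10). Of the acute phase genes, 10 of 15 tested members rose and 2 fell (10 and 2 adjusted over the list alone). Tested by camera, the adjusted p was 0.000503 at a median log2FC of 0.37, or adjusted p = 0.0263 with an estimated correlation. Hp rose from 5.12 ± 0.208 to 24 ± 0.725 FPKM (log2FC 2.03 ± 0.04, adjusted p = 3.07e-10).

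Inflammatory genes were lower in FFA_SIN than in NC, and more xenobiotic metabolism genes fell than rose, a list not past the threshold with an estimated correlation (camera adjusted p = 0.095). Of the NF-kB and cytokine genes, 3 of 35 tested members rose and 22 fell (3 and 22 adjusted over the list alone). The median log2FC was -0.32 and the camera adjusted p was 3.71e-06, or adjusted p = 0.00923 with an estimated correlation. Tnfaip2 and Nos2 fell from 28.6 ± 0.423 to 8.28 ± 0.243 FPKM (adjusted p = 2.52e-10) and from 16.4 ± 0.525 to 7.28 ± 0.134 FPKM (adjusted p = 1.86e-08). Of the xenobiotic metabolism genes, 4 of 18 tested members rose and 12 fell (4 and 12 adjusted over the list alone). At a median log2FC of -0.43, the camera adjusted p was 0.00117, or adjusted p = 0.095 with an estimated correlation. Abcb1a, a drug efflux pump, fell from 15.4 ± 0.34 to 5.21 ± 0.157 FPKM (log2FC -1.4 ± 0.04, adjusted p = 5.35e-09). Of the immediate early genes, 1 of 23 tested members rose and 17 fell (1 and 17 adjusted over the list alone). As a list these had a median log2FC of -0.22 and a camera adjusted p of 4.24e-05, or adjusted p = 0.105 with an estimated correlation. Myc fell from 57.6 ± 0.524 to 34.4 ± 1.13 FPKM (log2FC -0.73 ± 0.03, adjusted p = 2.37e-08). Of the clock genes, 2 of 14 tested members rose and 8 fell (2 and 8 adjusted over the list alone). Together they had a median log2FC of -0.2 and a camera adjusted p of 0.028, or adjusted p = 0.24 with an estimated correlation. The camera value was 0.0549 with trends on GC content and length removed. The NRF2 list stayed just outside (9 rose and 19 fell of 38 (9 and 20 adjusted over the list alone; camera adjusted p = 0.051)), at an adjusted p of 0.0455 without NC replicate 2, 0.0425 with replicate number as a block and 0.045 by limma-voom on recovered reads. Its member Hmox1 rose from 24.9 ± 0.994 to 80.7 ± 3.75 FPKM (log2FC 1.66 ± 0.04, adjusted p = 3.04e-09).

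Lists of oxidative phosphorylation, mitochondrially encoded and cytosolic ribosomal protein genes were higher in FFA_SIN than in NC at the preset correlation only (camera adjusted p = 0.207, 0.207 and 0.435 with an estimated one). Of the oxidative phosphorylation genes, 29 of 44 tested members rose and 1 fell (31 and 1 adjusted over the list alone). Tested by camera, the adjusted p was 2.98e-06 at a median log2FC of 0.16, or adjusted p = 0.207 with an estimated correlation. Of the mitochondrially encoded genes, 7 of 13 tested members rose and 0 fell (9 and 0 adjusted over the list alone). The median log2FC was 0.42 and the camera adjusted p was 0.00133, or adjusted p = 0.207 with an estimated correlation. The share of reads from mitochondria was also higher, at 4.72 ± 0.209% against 4.01 ± 0.08%. Of the cytosolic ribosomal protein genes, 25 of 45 tested members rose and 0 fell (25 and 0 adjusted over the list alone). At a median log2FC of 0.1, the camera adjusted p was 0.000202, or adjusted p = 0.435 with an estimated correlation. The subunit gene Rpsa, which has many pseudogenes, rose slightly (log2FC 0.15 ± 0.02, adjusted p = 0.000182). Hepatocyte identity genes split evenly (10 rose and 10 fell of 22 (10 and 10 adjusted over the list alone; camera adjusted p = 0.608)). The p53 targets did not pass (7 rose and 16 fell of 34 (7 and 16 adjusted over the list alone; camera adjusted p = 0.416)), and neither did cell cycle genes (10 rose and 16 fell of 47 (10 and 16 adjusted over the list alone; camera adjusted p = 0.269)). Matrix genes split (10 rose and 11 fell of 25 (10 and 11 adjusted over the list alone; camera adjusted p = 0.518)). Interferon-stimulated genes (5 rose and 5 fell of 15 (5 and 5 adjusted over the list alone; camera adjusted p = 0.445)) and histones (3 rose and 0 fell of 11 (3 and 0 adjusted over the list alone; camera adjusted p = 0.146)) did not pass.

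Among markers of other cell types in FFA_SIN against NC, the macrophage list did not pass (0 rose and 2 fell of 3 (0 and 2 adjusted over the list alone; camera adjusted p = 0.112)). The cholangiocyte list split (3 rose and 3 fell of 7 (3 and 3 adjusted over the list alone; camera adjusted p = 0.6)), with a median log2FC of 0 and a mean of -0.10. Krt7, a keratin of bile ducts, fell from 113 ± 2.75 to 55 ± 1.52 FPKM (log2FC -1.02 ± 0.03, adjusted p = 2.95e-09). Sox9, a factor of bile ducts and progenitors, rose from 12.6 ± 0.892 to 27.9 ± 1.04 FPKM (log2FC 1.08 ± 0.06, adjusted p = 2.82e-07). Des fell (log2FC -1.45 ± 0.05, adjusted p = 1.62e-08). Its list, with 0 risen and 1 fallen also when adjusted over the list alone, had a camera adjusted p of 0.051, and of 0.0345 without FFA replicate 3. It was 0.0387 by limma-voom on recovered reads and 0.0472 with median-of-ratios size factors.

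**Figure D3:**
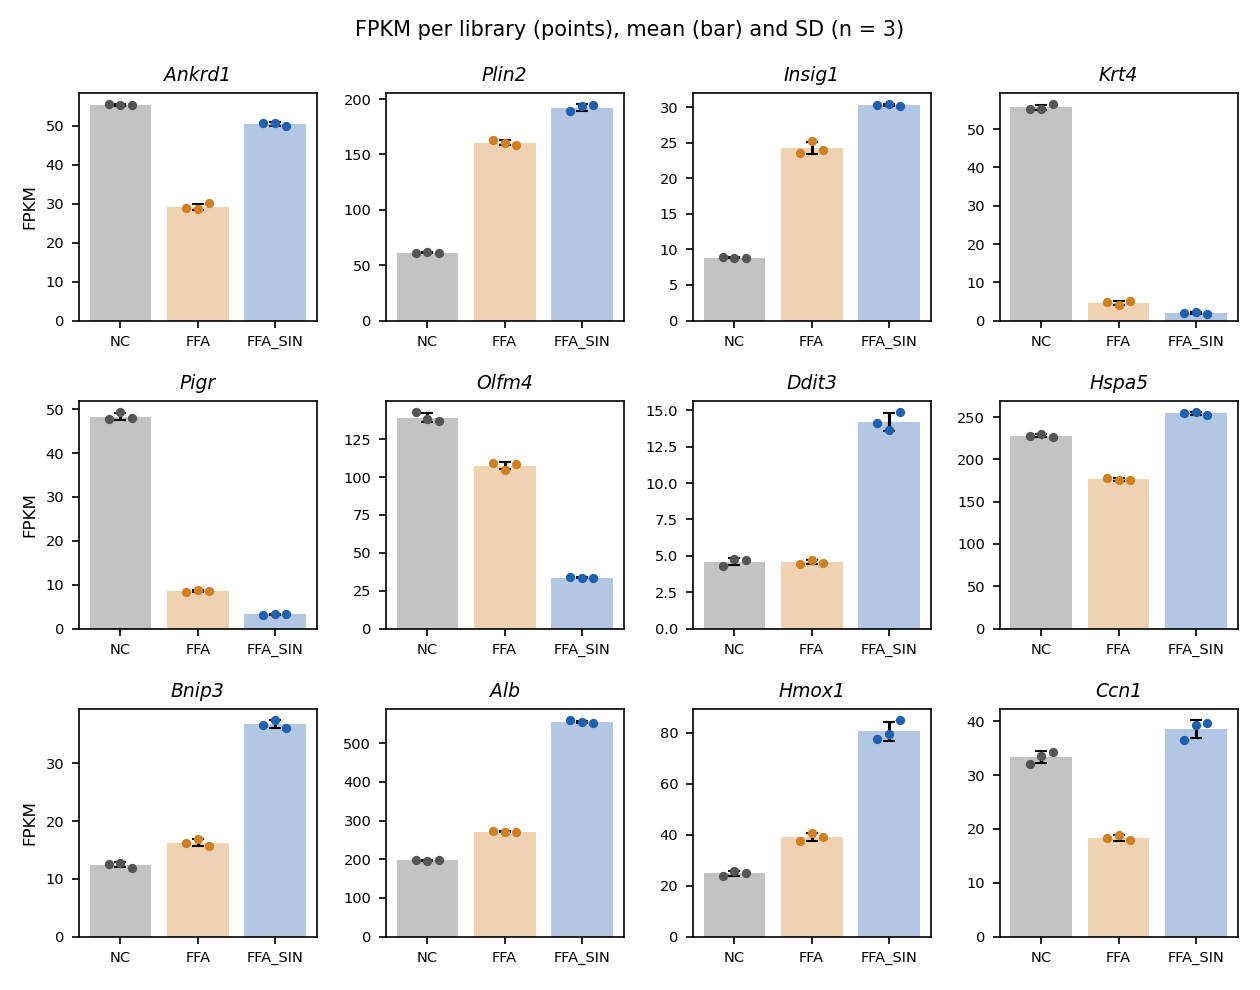
FPKM of 12 genes in each library (points) of NC, FFA and FFA_SIN, with the mean (bar) and SD (error bar, n = 3). Ankrd1, Ccn1 and Hspa5 are lowest with fatty acids alone, Krt4, Pigr and Olfm4 fall at each step, and Ddit3, Bnip3 and Alb are highest with sinomenine.

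Most genes changed by fatty acids (2370 of 4369) were not past the threshold in FFA_SIN against FFA. Of the 4369, 28.8% went further and 16.9% turned back. Of 1999 genes that changed in both FFA against NC and FFA_SIN against FFA, 740 (37.0%) changed in opposite directions and 1259 in the same direction. Of the opposite ones, 381 rose and then fell and 359 fell and then rose. Of the others, 561 rose at each step and 698 fell at each step. If the changes were independent, 386 and 297 genes would have gone in opposite directions, and 310 and 371 in the same. Both comparisons use the FFA libraries, which by noise alone pushes them apart. Across genes, which are not independent replicates, the fold changes had a Pearson r of 0.179. In 100 simulations of unchanged groups its mean was -0.504 and its highest value -0.426. Those simulations gave at most 1 gene in opposite directions and 0 in the same. Of the 4369 genes changed by fatty acids, 3367 (77.1%) were still changed in the same direction in FFA_SIN against NC, 858 were not past the threshold, and 144 had changed sign. These comparisons share the NC libraries, which by noise alone pushes them together. With each NC library in turn kept for FFA_SIN alone and the other 2 used for FFA, 3417 of 3822, 3309 of 3689 and 3292 of 3647 changed genes kept their direction.

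Among the clearest opposite changes were those in Ankrd1, Hspa5, Ccn1 and Aldh1a7. Ankrd1, a target of YAP, fell from 55.3 ± 0.169 to 29.2 ± 0.765 FPKM (log2FC -0.9 ± 0.02, adjusted p = 8.41e-09). It then rose to 50.4 ± 0.438 FPKM (log2FC 0.77 ± 0.02, adjusted p = 3.18e-08). Ccn1, a secreted matrix protein and also a YAP target, fell from 33.4 ± 1.16 to 18.3 ± 0.5 FPKM (log2FC -0.83 ± 0.04, adjusted p = 4.36e-07). It then rose to 38.5 ± 1.68 FPKM (log2FC 1.03 ± 0.04, adjusted p = 1.17e-07). Aldh1a7, an aldehyde dehydrogenase with a close paralog, rose from 17.3 ± 0.41 to 27 ± 0.732 FPKM (log2FC 0.62 ± 0.03, adjusted p = 5.77e-07). It then fell to 14.7 ± 0.382 FPKM (log2FC -0.84 ± 0.03, adjusted p = 8.83e-08), below NC. The clearest changes in the same direction were in Akr1b7, Pigr, Cd177, Muc13 and Alb. Akr1b7, an aldose reductase, fell from 281 ± 2.4 to 160 ± 1.62 FPKM (log2FC -0.81 ± 0.02, adjusted p = 4.56e-09). With sinomenine it went on to 85.1 ± 0.822 FPKM (log2FC -0.9 ± 0.02, adjusted p = 5.54e-09). Cd177, a neutrophil surface protein, fell from 30.2 ± 0.678 to 9.39 ± 0.504 FPKM (log2FC -1.59 ± 0.04, adjusted p = 6.6e-09). With sinomenine it went on to 3.34 ± 0.0798 FPKM (log2FC -1.26 ± 0.04, adjusted p = 3.68e-08). Muc13, a membrane mucin, fell from 15.8 ± 0.182 to 4.83 ± 0.143 FPKM (log2FC -1.52 ± 0.04, adjusted p = 3.46e-08). With sinomenine it went on to 1.20 ± 0.136 FPKM (log2FC -1.41 ± 0.04, adjusted p = 4.56e-08).

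**Figure D4:**
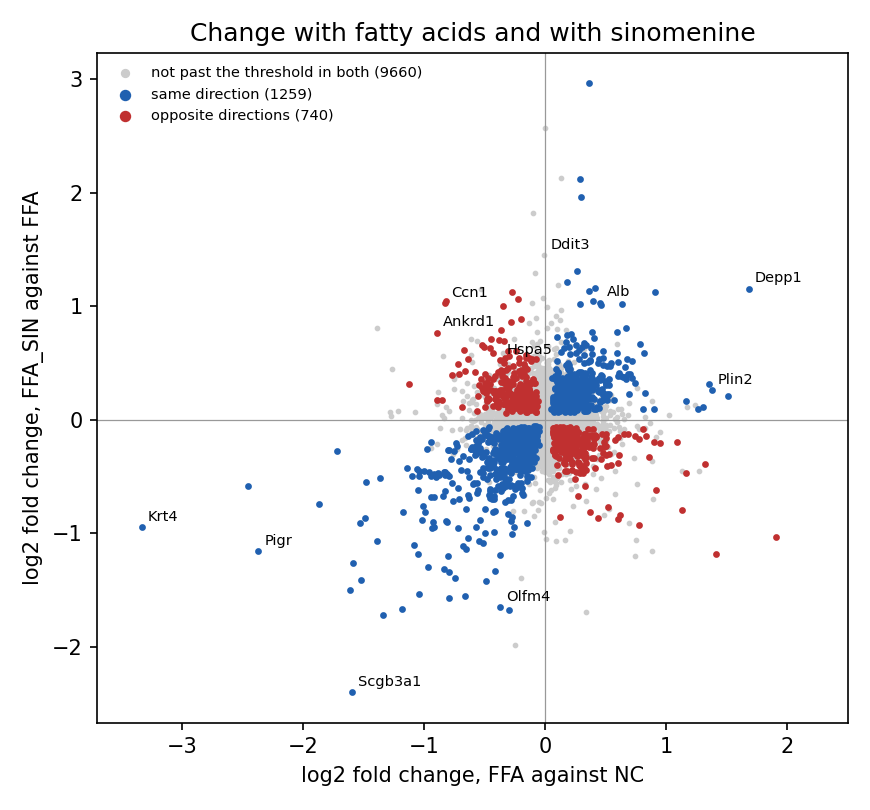
Log2 fold change (log2FC) on the log2(FPKM + 1) scale in FFA against NC (horizontal) and FFA_SIN against FFA (vertical) for each of 11659 genes, with 1259 genes past the threshold in both in the same direction, 740 in opposite directions and the rest in grey. Ankrd1, Ccn1 and Hspa5 lie in the opposite quadrants, and Pigr, Scgb3a1 and Alb in the same ones.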

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

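The setting with trends on GC content and length removed was chosen after seeing the data. Requiring a fold change of at least 2 on the log2(FPKM + 1) scale left 52 genes for FFA against NC, 63 for FFA_SIN against FFA and 188 for FFA_SIN against NC. Most changes were small, and that scale understates changes of low genes. Estimating the correlation within each list left 9, 8 and 9 changed lists, and fry, which does not compare a list with other genes, gave 29 for FFA_SIN against NC. Every other count stayed within 1.5 times the reported one, with 3867 to 4691, 3119 to 4024 and 5863 to 6519 changed genes under other scaling, filters, pseudocount, limma-voom on recovered reads and smaller fits. Leaving out each library in turn gave 3607 to 4268, 2968 to 3605 and 5334 to 5977 changed genes, 570 to 660 genes in opposite directions and 976 to 1162 in the same, and 16 to 19, 12 to 14 and 17 to 18 changed lists. With replicate number as a block, 4338, 3607 and 6006 genes changed. Deviations from the group means correlated at -0.015 to 0.174 between libraries with the same number and at -0.154 to 0.114 between others. These ranges overlap and show no clear pairing by number. The highest value was for replicate 3 of NC and of FFA_SIN, so a shared culture or batch cannot be excluded. Of 367 results for single named genes, 21 changed sides of the threshold under some setting and 0 reversed. Of the changed lists, 14 of 18, 12 of 14 and 17 of 17 held whichever library was left out, and none changed direction. Which of rises and falls outnumbered the other depended on the setting. Under median-of-ratios size factors there were 1871 rises and 1760 falls for FFA_SIN against FFA, and 3116 and 2842 for FFA_SIN against NC. Without a filter on low values FFA against NC had 1864 rises and 2003 falls. With trends on GC content and length removed it had 2219 and 2240, and FFA_SIN against NC had 3085 and 3082. No gene called both in these settings and in the reported fit changed direction. The planned edgeR and DESeq2 fits and TMM scaling were not used here, as the deposited values are FPKM, for which the plan set limma. A late trial of edgeR and DESeq2 on recovered reads was left out and is not reported here. Depth limits mainly genes near the filter of 1 FPKM.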

Other observations

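The tests of changed genes over other splits, of the shared FFA libraries, of a mixture of material, of a diluted subpopulation and of glycolytic enzymes alone were chosen only after the result was seen, and so was the measure of spread in the subpopulation test.

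With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and in each comparison only 1 of 10, the real grouping, gave as many. The real groups gave 4369, 3638 and 5977 changed genes (highest other split 1, 1 and 0) and 18, 14 and 17 changed lists (highest other 12, 7 and 12). Every other split mixes the groups, which widens the spread within them, so few changed genes were bound to follow. Camera still called up to 12 lists in such splits. They keep part of the group difference, so these list counts do not give a rate of false calls. Of 100 assignments of the 9 libraries to 3 groups, 3, the real one included, gave at least as many genes in opposite directions as the real 740. The highest other (3367) put the 3 NC libraries in the place of FFA and so follows the groups' own structure. Only 1 of 100, the real one, gave as many genes in the same direction as the real 1259 (highest other 144). Most assignments that mixed the groups gave 0 genes of either kind, because mixing widens the spread within groups. These shares therefore show that the groups differ and cannot decide whether the changes share a direction.

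With sinomenine, 28.8% of the genes changed by fatty acids went further in the direction they had taken. Shared FFA libraries alone do not account for it, since the covariance of the fold changes was 0.00768, against -0.00208 at the highest in 100 simulations of unchanged groups, and it was 0.00772 after trends on GC content and length were removed. FFA libraries that were a mixture of NC and FFA_SIN material would place every gene between those groups, yet 37% of the genes changed at both steps went in opposite directions. What stays open, untested, is an effect of sinomenine along the same path or a longer time in culture or with fatty acids in the FFA_SIN group. The labels give culture hours for FFA_SIN only, so the groups and culture time cannot be set apart by any test here.

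Of 127 genes that fell at least 2-fold from NC to FFA_SIN, Krt4, Pigr, Ltf, Scgb3a1 and Olfm4 among them, 117 fell at each step. They were picked by their total fall, the sum of the steps, so this count is not independent evidence of falls at each step. The 61 genes that rose at least 2-fold were not examined in this way. If a single subpopulation of cells had been diluted step by step, each gene would have lost the same share of its total fall with fatty acids alone, but the median share was 65.3% with a 10th to 90th percentile range of 37.0% to 84.4%. The median absolute deviation of the share was 7.56 median standard errors, against at most 1.4 in 200 draws with a common share, so dilution of such cells does not account for the whole pattern, though it may account for part. The SD of the share was tried earlier and set aside, at 7.29 standard errors, because draws with a common share reached 14.27. GC content and gene length do not account for it either, as 96.9% of the genes still fell 2-fold after their trends were removed, and a change in the cells' own state under fatty acids and sinomenine, or with time in culture, stays open.

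Glycolysis and hypoxia genes rose with sinomenine, 24 of 32. With trends on GC content and length removed, the list kept an adjusted p of 6.6e-11. Nor was it a matter of glycolytic enzymes alone, because of the 14 other members 11 rose and 1 fell, at a median log2 fold change of 0.43. That median lay 3.09 bootstrap standard errors above 0. The bootstrap drew members, which are not independent replicates, and does not measure the spread between libraries. The part set aside as enzymes also held the glucose transporter Slc2a1 and Pdk1. Less oxygen reaching the cells, a direct effect of sinomenine and a longer culture past confluency are possible explanations that no value here tells apart. As a biological hypothesis found and tested on the same data, hypoxia signalling could be checked by protein levels of its transcription factor and by culture oxygen.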
